A study of Mus musculus with 139 samples.

How the data were processed

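Single-cell RNA libraries were sequenced on an Illumina HiSeq 2500 per the labels, and each sample is 1 cell. The authors deposited 1 table of raw counts per gene for 139 cells, with 55335 lines named by gene identifier. Reads were trimmed with Trimmomatic, aligned with HISAT2 to GRCm38 (mm10) and counted with featureCounts of Subread 1.4.6, per the submitters' processing notes; the notes name the tools, and the role of each is inferred. Strandedness, the treatment of reads that map to several places and the use of molecular identifiers are not given in the sources used here. Reads of genes with near-identical copies or many pseudogenes, such as ribosomal protein and glycolysis genes, could therefore be lost or split.

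Each column was assigned to the sample whose title it matches, and 0 columns of values stayed unused. Gene identifiers were looked up in the GENCODE M21 annotation of GRCm38, where 54587 matched with their version and 55154 without it. The 181 lines without a symbol held 0.00885% of the counts, counted toward the totals and stayed out of lists and named genes, and 107 symbols occurred more than once. No genome sequence was used.

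Groups were formed from the labelled cell type and region. Because no label names an animal, each of the 6 groups counted as 1 sample and cells were not treated as replicates, so no test between groups was run. Counts were summed over the cells of a group, scaled with the TMM method of edgeR 4.0.16 and given as CPM, and differences are log2 of the ratio of (CPM + 1), which understates the difference of low genes. OHCs were compared with IHCs in each of 3 regions and as the mean of the 3, and base with apex in each type. Intervals of a level or share are exact Poisson or Clopper-Pearson intervals at 95%. For a gene with 0 counts, 3 counts over the group were taken as the limit. To compare shares of cells with a read, each cell was thinned to 582635 counts, the percentile 10 of all totals, which left 125 cells.

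Before the data were examined, 26 gene lists were fixed: general hair cell, IHC markers, OHC markers, mechanotransduction complex, stereocilia bundle, ribbon synapse, potassium channels, calcium binding and transport, efferent synapse, lateral wall and cortical cytoskeleton, nuclear respiratory chain, glycolysis, antioxidant defence, chaperones, immediate early, apoptosis and p53, apex-high and base-high in the developing duct, supporting cells, neurons and glia, blood and immune, mesenchyme and bone, stria vascularis, pericytes and endothelium, ribosomal proteins and mitochondrially encoded. Members needed at least 5 CPM in 1 or more groups, which 15004 genes passed. The median of a list was placed among 10000 random lists of the same size, matched on mean expression in 20 bins, which describes these libraries and is not a p-value. Intervals of a list median come from resampling its members 2000 times and say only how much it rests on single members. Some genes belong to 2 lists, such as Otof, Slc17a8, Ocm and Myo7a.

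Single genes were named by a rule fixed at the same time. It left out predicted, ribosomal, mitochondrial and pseudogene symbols and required at least 10 CPM in the higher group and reads in at least 50% of its cells. For OHCs against IHCs a gene had to differ 2-fold or more in the same direction in each region, pooled and in the mean of the cells, and the 10 with the largest mean log2 ratio were named in each direction. For base against apex it had to differ 2-fold or more pooled and in the mean of the cells, in the same direction in each title-number series with at least 5 cells per group, with the middle no more than 0.5 log2 outside the range. The 10 with the largest smaller value of these 2 were named in each direction. For both types together the 5 largest in each direction were named, and the 3 largest of each opposite kind. A set of 14 hair cell genes and the extremes of each list could be named as well. Some of the genes picked are not reported here. Lowest levels or shares picked out from the named genes were chosen after their values were seen.

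The steps were tested on simulated counts drawn once from the real means, totals and spread between cells, with genes independent of each other. For OHCs against IHCs (7742 genes), true 2-fold, 4-fold and 8-fold differences gave median estimates of 0.95, 1.92 and 3.02 on the log2 scale, in the right direction for 70.2%, 85.1% and 90.9% of genes. The naming rule took 1.49%, 4.48% and 21.2% of these genes and 0.172% of the unchanged ones. Of the 10 genes it ranked per direction, 7 on the OHC side and 9 on the IHC side were truly changed. With no difference between base and apex, 7.60% of genes met the rule in IHCs and 10.8% in OHCs. Among lists of 18 genes (13260 genes in this step), 3.5% in IHCs and 6% in OHCs lay outside the middle 95% of random lists with no shift. With a shift of 1 log2 unit, 53% and 47.5% did.

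Alternatives fixed before the data were examined were equal weight per cell, the median of the cells, plain CPM, size factors of DESeq2 1.42.0, 5 CPM added in place of 1, no filter or one of 20 CPM, each title-number series alone, the removal of the deepest cell of each group, of 26 shallow cells or of 1 possible repeat, and equal depth. The possible repeat, a title that extends the name of another cell, had a Pearson correlation of 0.188 with that cell, below the highest pair at 0.735, and both were kept. Added after seeing the data were the average of both series, the removal of 8 cells with more counts of the other type's markers, apical IHCs as deep as the shallowest basal one, and OHCs without the base. The removal by markers was not applied to the marker comparison between types, which it would decide by construction. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 and R 4.3.3 were used.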

Results

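RNA was sequenced from single hair cells of the mouse cochlea, taken between postnatal days 14 and 16. Inner hair cells (IHCs) are the receptor cells that pass sound signals to the auditory nerve, and outer hair cells (OHCs) change length and amplify the vibration that reaches them. The labels give each cell a type and 1 of 3 regions of the cochlear spiral: the apex, tuned to low frequencies, the middle, and the base, tuned to high frequencies. There were 34 IHCs from the apex, 34 from the middle and 19 from the base, and 21, 23 and 8 OHCs from the same regions. The design asks how hair cells differ between the types and along the spiral.

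Counts per cell ran from 71027 to 13576942, and detected genes from 681 to 27575. The median totals of IHCs were about 3597250 in the apex, 6158040 in the middle and 6842130 in the base. Those of OHCs were about 4092900, 1871530 and 2522430. The 8 basal OHCs summed to 28574809 counts, of which 1 cell held 30.9%, while the other groups summed to between 94869815 and 199944360. The labels name no animal, so each group is 1 sample and no difference below has a replicate check. The sources used here name no molecular identifiers, so intervals of a gene's level or ratio cover counting error only. They leave out the spread between cells, which was far larger. Intervals of a list median come from resampling its members.

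**Figure D1:**
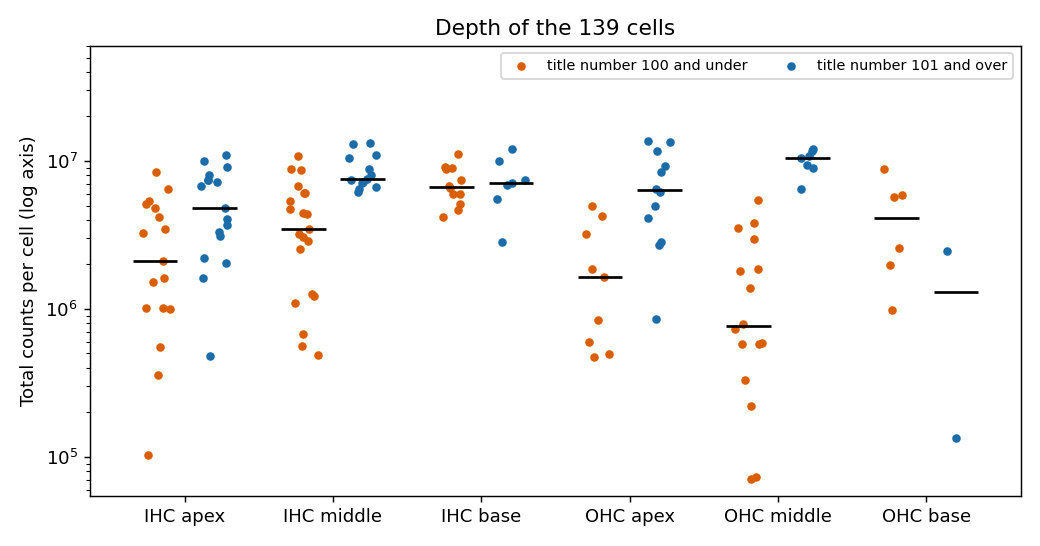
Total counts per cell (log axis) in the 6 groups; each point is 1 cell, colours give the title-number series, and bars are medians. The 8 basal OHCs had a median of about 2522430 counts, against about 6842130 in the 19 basal IHCs.

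The titles carry numbers whose meaning is not given in the sources used here, and these were split into 2 series, 81 cells numbered 100 or less (the lower series) and 58 numbered above 100 (the higher series). The first principal component of the cells held 23.8% of the variance over 5416 genes, and its medians separated the series in all groups except basal OHCs. It also correlated with the log of total counts (0.615) and of detected genes (0.454), so it does not separate series from depth. In middle IHCs the medians were −69.1 for the lower numbers and 194.7 for the higher; in basal OHCs they were −65.2 and −74.1. Values within each series are therefore given beside many of the pooled ones, though not all. The higher series holds only 2 basal OHCs, 1 of which held 94.9% of their counts, so its values for basal OHCs are in effect those of 1 library. All genes with symbols starting mt-, a wider set than the protein-coding list of mitochondrially encoded genes, held 16.9% and 14.8% of the counts of these 2 cells. CT010467.1 held 26.1% and 29%. The other 6 had at most 4.98% and 1.43%. High shares were not limited to basal OHCs. In the higher series they were 16.0% and 28.6% in basal IHC cell 2 and 11.5% and 12.9% in middle OHC cell 1. Differences are given as log2 of the ratio of pooled scaled counts (CPM) with 1 CPM added. Across 15004 genes the median difference was −0.59 for OHCs against IHCs (mean of the regions), −0.02 for basal against apical IHCs and −0.72 for basal against apical OHCs. Gene lists were placed among 10000 random lists of equal size and expression, which carry the same shift.

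Otof, which encodes the calcium sensor of vesicle release at the IHC synapse, and Slc17a8, which encodes a vesicular glutamate transporter, were higher in IHCs than in OHCs in each region. Otof stood at 5448 CPM (95% Poisson interval 5436 to 5459) in apical IHCs and at 213 (210 to 216) in apical OHCs. In the middle it stood at 3445 and 25.5 CPM, and in the base at 6506 and 0.199 CPM (0.0543 to 0.51). Slc17a8 was at 430, 777 and 706 CPM in IHCs from apex to base, against 4.34, 0.137 and 0.0996 CPM in OHCs. Ocm, which encodes the calcium-binding protein oncomodulin, was at 5391 CPM (5376 to 5405) in apical OHCs and 298 (295 to 301) in apical IHCs. It stood at 3294 against 140 CPM in the middle and 4413 against 1.30 CPM in the base. Slc26a5, which encodes prestin, the motor protein of the OHC lateral wall, was at 697, 207 and 34.3 CPM in OHCs, against 48.3 and 1.44 CPM in apical and middle IHCs and 8 counts in basal IHCs. A single basal OHC held 95% of the Ocm counts and 98.7% of the Slc26a5 counts of its group. Among middle OHCs, the median cell of the lower title numbers (16 cells) had 0 CPM of Slc26a5 and 36.5 CPM of Ocm. That of the higher numbers (7 cells) had 252 and 4450 CPM. Without the deepest cell of each group, the mean log2 ratio over regions was 5.13 in place of 6.54 for Ocm and 3.53 in place of 5.10 for Slc26a5. In the higher and the lower series that ratio was 5.25 and 6.93 for Ocm, 3.31 and 6 for Slc26a5, −8.10 and −8.63 for Otof and −7.74 and −9.80 for Slc17a8.

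The markers of each type fixed before the data were examined followed these genes. All 10 IHC markers were at least 2-fold lower in OHCs, with a list median of −3.86 (95% interval over members −8.06 to −2.34), below every random list. The median was −4.37 in the higher series and −4.10 in the lower. Of 11 OHC markers, 9 were at least 2-fold higher in OHCs and none lower, with a median of 2.04 (1.33 to 5), above every random list. This median was 1.41 in the higher series, with 6 higher and Strip2 (−1.11) lower, and 5.28 in the lower, with 9 higher and none lower. Chrna9, a subunit of the acetylcholine receptor at OHC efferent synapses, had the smallest difference at 0.38. In the base alone, Kcnn2 (−2.0), Sri (−1.03) and Chrna9 (−0.81) were among the OHC markers that were lower in OHCs than in IHCs. Other genes always examined included Myo7a (−1.51), the hair cell myosin, Pou4f3 (−2.42), a hair cell transcription factor, and Tmc1 (0.21), a part of the transduction channel. The calcium-binding genes Calb1, Calb2 and Pvalb were at −0.16, −1.64 and −0.75. Tmc1 was at −2.43 in the higher series and 1.36 in the lower, Calb1 at −0.94 and 0.20, Pvalb at 0.20 and −2.08, Calb2 at −1.35 and −3.85, Pou4f3 at −3.0 and −5.41 and Myo7a at −1.54 and −1.61. The potassium channel Kcnma1 was at −2.15, with −0.67 and −7.28 in the series, and the receptor subunit Chrna10 at 1.74, with 1.74 and 0.14.

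**Figure D2:**
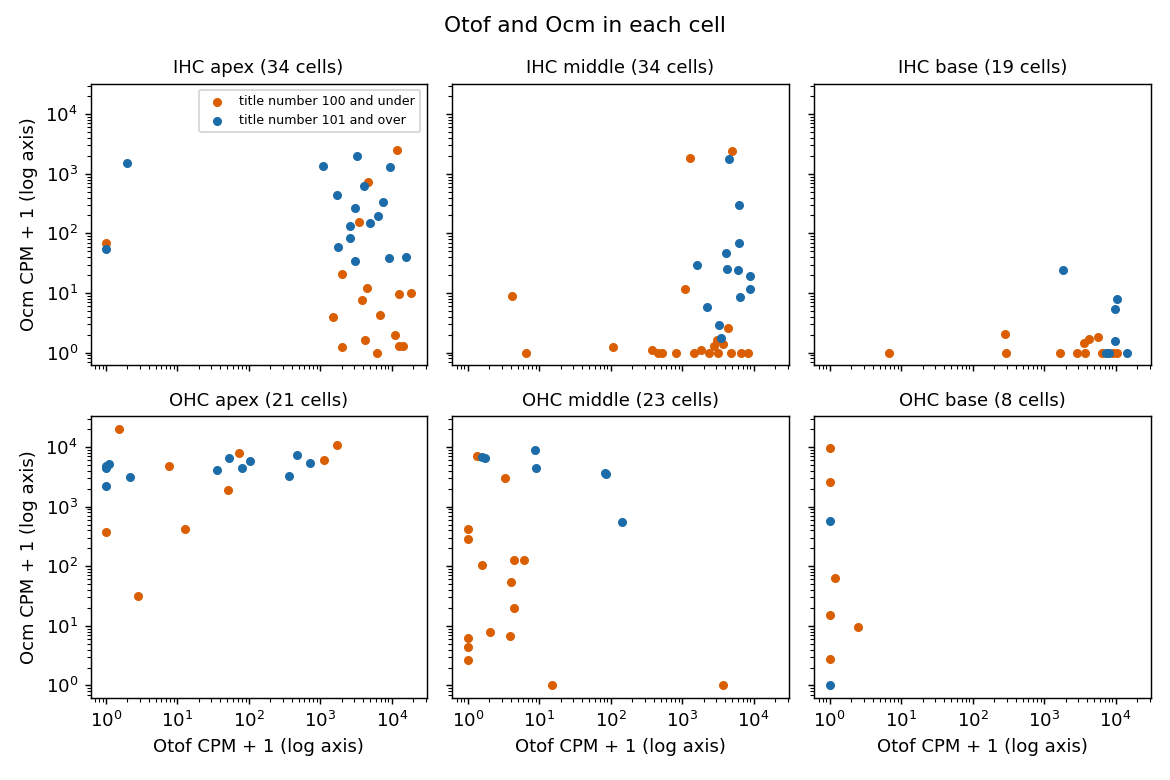
Ocm against Otof in each cell (CPM + 1, both axes log), 1 panel per group, with colours for the title-number series. Pooled Otof was 5448 CPM in apical IHCs and 213 in apical OHCs, while pooled Ocm was 298 and 5391 CPM, and single cells in both types carried reads of the other type's gene.

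By the rule of size, the 10 genes higher in OHCs were Ocm (6.54), Bmp3 (6.21), Slc26a5 (5.10), Ikzf2 (5), Hs3st3b1 (4.91), Wls (4.71), Rnf213 (4.2), Dnm3 (3.37), Cachd1 (3.15) and Srpk2 (3.15). Ikzf2 encodes a zinc finger transcription factor of OHCs, Bmp3 a secreted growth factor and Dnm3 a dynamin. Wls and Srpk2 turned in the higher series, to −0.84 and −1.01, and the other 8 kept their direction in both series. In the base, 1 OHC held 99.2% of the Bmp3 counts, 99.4% of those of Ikzf2 and 99.5% of those of Wls, and 94.6% of those of Srpk2. The 10 genes higher in IHCs were Slc7a14 (−9.28), Slc17a8 (−8.36), Atp2a3 (−8.06), Otof (−8.03), Prkd1 (−7.85), Kifap3 (−6.99), Ripor3 (−6.81), Rps6ka2 (−6.75), Ptprz1 (−6.75) and Btg2 (−6.74). Slc7a14 encodes a membrane transporter of the cationic amino acid family and Atp2a3 a calcium pump of the endoplasmic reticulum. All 10 kept their direction in both series. In simulated data of 7742 genes, the largest unchanged gene that the rule ranked reached 3.18 on the OHC side, above Cachd1 and Srpk2 here, and 2.93 on the IHC side.

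In GRCm38 coordinates, Otof spans 30367062 to 30461932 on chromosome 5, minus strand, and Slc17a8 spans 89574020 to 89621253 on chromosome 10, minus strand. Ocm spans 144019804 to 144026670 and Slc26a5 spans 21810655 to 21865604, both on the minus strand of chromosome 5. All are protein-coding, and counts are per gene. Of 82 named genes placed, 2 share exonic bases with a gene on their own strand (Cox17 with Gm21987 and Cenpb with Spef1) and 21 with a gene on the opposite strand. The latter include Ikzf2, Srpk2, Rnf213, Dnm3 and Ripor3 in this comparison and Ikbkg, Chrna10, Kcnma1, Stard9 and Golph3 below. Whether the counting used strand is not given in the sources used here, so reads of such pairs cannot be separated.

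Among other gene groups, potassium channel genes had a median of −1.79 (percentile 0.75 among random lists), with 11 of 16 at least 2-fold lower in OHCs and 2 higher. Kcna10 (−5.06) and Kcnab1 (−4.33) were lowest and Kcnn2 (1.5), the calcium-activated channel of OHC efferent synapses, was highest. The list median was −2.09 in the higher series and −0.35 in the lower, where it lay at percentile 67.2. Ribosomal protein genes were at 0.73, with 29 of 81 at least 2-fold higher and 6 lower, and turned to −0.56 in the lower series, where the list still lay at percentile 99.6. Mitochondrially encoded genes were at 0.72 (percentile 98.7). Nuclear genes of the respiratory chain were at −0.03, above the shift of all genes (percentile 99.9, and 95.7 in the lower series), and genes of the lateral wall and cortical cytoskeleton at 0.42 (percentile 98.0) with 4 of 15 higher and 5 lower. As the mean of the regions, lists of other tissues were also higher in OHCs: blood and immune genes at 1.43, neurons and glia at 1.18 and mesenchyme and bone at 0.69. In the apex alone, blood and immune genes were at 1.13 (percentile 98.1). Neurons and glia (0.31, percentile 69.8) and mesenchyme and bone (0.09, percentile 61.2) lay within the middle 95% of random lists there. The list of neurons and glia turned to −0.34 in the lower series and that of the lateral wall to −0.18, both within the middle 95% of random lists there. Col3a1 and Dcn, genes of connective tissue, were at 3.11 and 3.77.

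As the mean of the 3 regions, the remaining 16 lists lay within the middle 95% of random lists when pooled. Their medians were −0.94 for calcium binding and transport, −0.98 for the mechanotransduction complex, −1.28 for apoptosis and p53, −0.94 for supporting cells, −0.90 for general hair cell genes and −0.70 for chaperones. They were −0.71 for the stereocilia bundle, −0.64 for the ribbon synapse, −0.71 for glycolysis, −0.67 for immediate early genes, −0.09 for pericytes and endothelium and −0.40 for antioxidant defence. The stria vascularis stood at 0.52, the efferent synapse at 0.38, and the apex-high and base-high lists of the developing duct, with 1 member each past the filter, at −0.82 and −2.59. In single series, the mechanotransduction complex lay below the range of random lists in the higher (−2.06, percentile 1.95) and calcium binding and transport in the lower (−2.13, percentile 2.15). In single regions, immediate early genes lay below that range in the apex (−3.13) and the middle (−1.8). So did supporting cells in the apex (−0.90), apoptosis and p53 in the middle (−1.34) and the stereocilia bundle in the base (−3.08). Calcium binding and transport lay above it in the apex (0.84) and below it in the middle (−1.1). The mechanotransduction complex lay above it in the apex (1.49) and below it in the base (−3.24). Across genes, the difference between the types correlated only weakly between regions, with Pearson values of 0.116 for apex and middle, 0.0916 for apex and base and 0.164 for middle and base. Genes are not independent replicates.

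**Figure D3:**
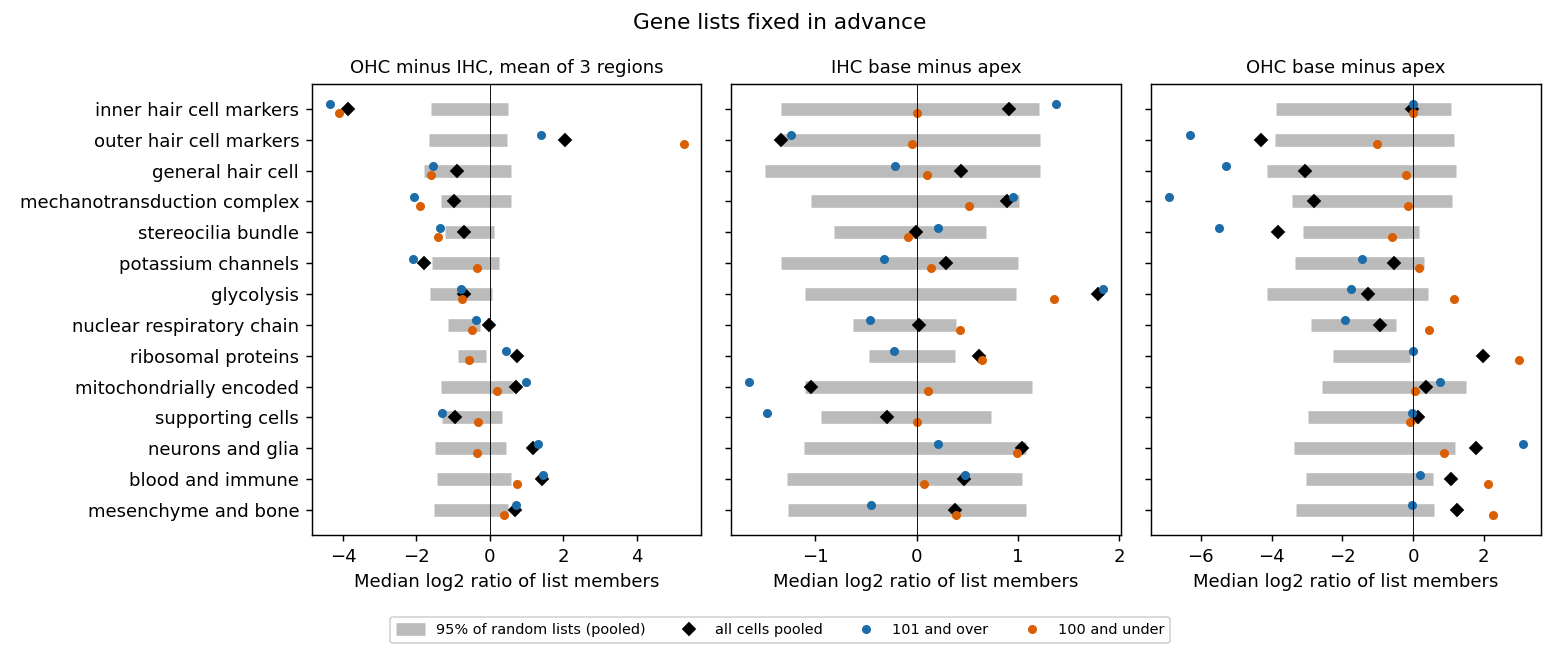
Median log2 ratio of 14 of the fixed gene lists in the 3 comparisons; diamonds pool all cells, circles are the 2 title-number series, and grey bars hold 95% of random lists for the pooled values. Glycolysis in basal against apical IHCs stood at 1.79 pooled, 1.84 in the higher series and 1.35 in the lower.

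Basal IHCs had higher levels of genes of glycolysis, the pathway from glucose to pyruvate and lactate, than apical IHCs. The list median was 1.79 (1.10 to 2.40 over members), at percentile 99.9, and 14 of 18 members were at least 2-fold higher, 1 lower; in the higher series these were 13 and 1, in the lower 10 and 4. Ldha, which encodes a lactate dehydrogenase subunit, stood at 82.7 CPM (81.2 to 84.3) in the base and 1.70 (1.5 to 1.92) in the apex, and Tpi1, a triosephosphate isomerase, at 194 (191 to 196) and 11.4 (10.9 to 12). Pfkp, a phosphofructokinase subunit, went the other way at 2.40 and 32.1 CPM, and Pfkm was at 0.43. The list median was 1.84 in the higher series and 1.35 in the lower, both above the middle 95% of random lists. The difference of the cells' medians was smaller, 0.48, still at percentile 99.9, and 1 basal cell held 72.5% of the Ldha counts.

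OHC markers were lower in basal than in apical IHCs, with a median of −1.34 (−5.54 to 0.07) at percentile 2.42, 7 of 11 at least 2-fold lower and 1 higher. Ocm (−7.02), Ikzf2 (−5.71) and Slc26a5 (−5.54) were among the lowest and Lmod3 (1.04) the highest. The median was −1.24 at percentile 4.33 in the higher series and −0.04 at percentile 49.1 in the lower, so it lay within the middle 95% of random lists in each. In the lower series 3 markers were lower and none higher. Ocm was at −7.07 and −6.16 in the higher and the lower series, Ikzf2 at −5.70 and −4.69, Lbh at −1.33 and −1.66 and Slc26a5 at −6.43 and 0.06. It lay there too when each cell counted alike (−0.69), after thinning to equal depth (−0.91) without the deepest cell of each group (−1.26) and with both series averaged (−0.64). The difference of the cells' medians was 0, at percentile 46.5. Ribosomal protein genes stood at 0.61 (percentile 99.8), with 31 of 81 higher and 16 lower, and at −0.23 in the higher series, within the range of random lists (percentile 46.9), and 0.65 in the lower.

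The other 23 lists lay within the middle 95% of random lists in IHCs when pooled, and 5 of them left it in 1 series. In the higher series these were supporting cells at −1.48 (percentile 0.15), mitochondrially encoded genes at −1.66 (0.8), IHC markers at 1.37 (99.5) and the mechanotransduction complex at 0.95 (99), and in the lower the nuclear respiratory chain at 0.42 (99.9). Among the pooled medians, genes of neurons and glia were at 1.03 (percentile 96.9), the mechanotransduction complex at 0.89, the ribbon synapse at 0.57, IHC markers at 0.91 and apoptosis and p53 at 0.84. Mitochondrially encoded genes were at −1.05, immediate early genes at −1.29, chaperones at −0.65, antioxidant defence at −0.61, supporting cells at −0.29 and the efferent synapse at −0.33. The stereocilia bundle was at −0.01, the nuclear respiratory chain at 0.03, calcium binding and transport at 0.19, potassium channels at 0.28, the lateral wall at 0.34 and general hair cell genes at 0.43. Blood and immune genes were at 0.46, mesenchyme and bone at 0.38, the stria vascularis at −1.37 and pericytes and endothelium at 0.04. The 1 member past the filter of each list of the developing duct was Nr2f1, at 0.05, and Inhba, at −3.46. The calcium buffer gene Pvalb was at 558 CPM (554 to 562) in basal and 34.9 CPM (33.9 to 35.8) in apical IHCs, and at 1.67 and 5.23 on the log2 scale in the higher and the lower series.

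Among the single genes picked by size were Lyar (7.88), Hhat (6.78), Aqr (6.49), Chd5 (6.43), Fer1l5 (6.35), Slc34a3 (6.30), Mapre3 (6.06), Stard9 (5.84) and Scamp5 (5.78) on the basal side. Scamp5 encodes a secretory carrier membrane protein. One cell held between 34.8% (Stard9) and 98.8% (Aqr) of each gene's counts in basal IHCs, and the median basal cell had at most 3.51 CPM (Scamp5). On the apical side they were Ocm (−7.02), Zfp317 (−6.51), Col27a1 (−6.36), Topors (−6.22), Cox17 (−6.21), Scg3 (−6.21), Socs2 (−6.18), Id2 (−5.79), Bhlhe41 (−5.77) and Ikzf2 (−5.71). Id2 and Bhlhe41 encode helix-loop-helix transcription regulators and Socs2 a regulator of cytokine signalling. The median apical IHC had 538 CPM of Id2 and 132 CPM of Socs2, against 0.155 CPM of Topors. Stard9 fell to 0.36 in the higher series and Cox17 to −0.48 in the lower. The rule required the same direction in both series, so their agreement is no further evidence. In data simulated with no regional difference, 7.60% of 7742 genes met the rule of size in IHCs, with ranked values up to 4.26 on the basal side and 7.41 on the apical side. The apical genes therefore lay within what the rule returns by chance. The basal genes lay above the simulated value, but 1 draw with independent genes does not exclude chance for them.

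In the pooled counts, most genes of the stereocilia, the actin-filled projections that sense sound, were lower in basal than in apical OHCs, but the list as a whole held a similar share of all counts. That share was 1.13% in the base and 1.30% in the apex pooled, and 1.33% and 1.21% in the median cell. Most of it was Actb, singled out after its values were seen, with 241219 of 28574809 counts in the base and 854252 of 102704914 in the apex. The list median was −3.82 (−4.86 to −2.56) at percentile 0.12, with 21 of 28 members at least 2-fold lower and 2 higher. In the lower series, which holds 6 of the 8 basal cells, 11 were lower and 4 higher, so less than a majority were lower there, and in the higher series 24 were lower and none higher. Random lists were low in the higher series too: the middle 95% of those matched to the stereocilia list ran from −5.02 to −1.17. Clic5 and Ptprq, which encode proteins of the stereocilia base, were at 222 and 113.3 CPM in the apex and at 3 and 0 counts in the base, and the ratio of base to apex was 0.000673 (0.000139 to 0.00197) for Clic5. The 0 counts of Ptprq in 28574809 allow a level of up to 0.00132 times that of the apex, taking 3 counts over the group as the limit. Rdx (1.95) and Espn (1.5), which encode the actin-binding proteins radixin and espin, were higher in the base, where 1 cell held 99.1% of the Espn counts, but turned in the higher series, to −0.64 and −8.51. The median was −5.47 in the higher series and −0.60 in the lower, below the middle 95% of random lists in both, and −0.16 as a difference of the cells' medians. With 4 members at 0 in the base held at 3 counts, the median stayed at −3.82.

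Other hair cell genes were lower in the base as well. OHC markers had a median of −4.29 (−4.83 to −0.31) at percentile 1.10, with 8 of 11 lower and none higher, and −6.30 in the higher series, with all 11 lower, and −1.03 in the lower, with 6 lower and 1 higher. The middle 95% of random lists matched to them ran from −5.90 to −0.03 in the higher series and from −0.88 to 1.64 in the lower. Of the markers, Chrna10 (−6.0) was lowest when pooled, and Ocm (−0.29) and Strip2 (−0.08) were nearest to 0, the latter at −9.35 and 1.92 in the higher and the lower series. Pou4f3 was at 650 CPM (645 to 655) in the apex and 4.13 (3.29 to 5.12) in the base, Tmc1 at −2.5, Myo7a at −5.13 and Chrna9 at −3.17. In the higher and the lower series Pou4f3 was at −9.84 and −4.57, Tmc1 at −8.86 and −3.37, Myo7a at −4.47 and −0.21, Chrna9 at −3.83 and −1.03 and Chrna10 at −6.92 and 0.27. General hair cell genes had a median of −3.05 and the mechanotransduction complex −2.81, within the middle 95% of random lists when pooled, with 8 of 9 and 10 of 12 members at least 2-fold lower. General hair cell genes were at −5.30 (percentile 7.65) in the higher series, with 8 lower, and at −0.21 (percentile 14.2) in the lower, with 4 lower and 2 higher. The mechanotransduction complex was at −6.90 (percentile 0.2) in the higher series, below that range, and at −0.14 (percentile 31) in the lower. Lhfpl5, which encodes a part of the transduction complex, was at 1357 CPM in the apex and 6 counts in the base. Nearly all of this came from the higher series (−10.96), since the lower had 29 counts in 2 of 9 apical cells and stood at −0.78.

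Genes of other tissues stood high in the same basal OHCs. The median was 1.79 for neurons and glia (percentile 99.5), 1.25 for mesenchyme and bone (99.4) and 1.08 for blood and immune genes (99.4), with 8 of 13, 7 of 13 and 6 of 12 members higher. Hbb-bs, a beta globin, was at 13780 CPM (13730 to 13830) in basal and 338 (334 to 341) in apical OHCs, and Col1a1, a collagen of bone and connective tissue, at 4.68 on the log2 scale. Hbb-bs was at 0.49 and 5.51 and Col1a1 at 1.53 and 4.15 in the higher and the lower series. In the higher and the lower series the medians were 3.10 and 0.88 for neurons and glia, −0.02 and 2.25 for mesenchyme and bone and 0.19 and 2.12 for blood and immune genes; that of neurons and glia lay at percentile 85.2 in the lower series and that of mesenchyme and bone at 96.1 in the higher, both within the range. Supporting cell genes were at 0.14 (percentile 97.0), the stria vascularis at −3.68 and pericytes and endothelium at 0.48. Ribosomal protein genes had a median of 1.97 (1.29 to 2.48), above every random list, with 52 of 81 higher and 17 lower. That median was −0.01 in the higher series, with its 2 basal cells, still above every random list, with 29 higher and 33 lower, and 3.01 in the lower, with 60 and 12.

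The other lists lay within the middle 95% of random lists in OHCs when pooled. Chaperones were at −2.78, the efferent synapse at −2.97, calcium binding and transport at −2.35, the ribbon synapse at −1.0, potassium channels at −0.53 and glycolysis at −1.28, the last turning to 1.15 in the lower series, above the range of random lists (percentile 97.9). IHC markers were at −0.04, the lateral wall at 0.07, mitochondrially encoded genes at 0.38, the nuclear respiratory chain at −0.94, apoptosis and p53 at 0.11, antioxidant defence at −0.06 and immediate early genes at 0.16. The nuclear respiratory chain lay above the range of random lists in both series, at −1.91 (percentile 99.5) in the higher and, turned, at 0.46 (percentile 100) in the lower. In the higher series mitochondrially encoded genes (0.77), immediate early genes (0.27) and supporting cells (−0.04) lay above it as well, and in the lower the efferent synapse (−0.44) below it. Nr2f1 was at −1.65 and Inhba at −4.68.

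By the rule of size the basal genes were Itpripl1 (10.22), Maml3 (9.22), Sema3b (8.58), Galnt17 (8.05), Tomm40 (7.70), Ppp2r5e (7.68), Efcab2 (7.67), Dse (7.66), Cenpb (7.61) and Mafa (7.50). One of 8 cells held between 47.2% (Tomm40) and 99.9% (Itpripl1) of their counts. Tomm40, Maml3, Galnt17 and Dse turned in the higher series, to −0.14, −0.20, −0.29 and −1.28, Itpripl1 and Cenpb fell to 0.89 and 0.94 there, and Efcab2 to 0.11 in the lower. The apical genes were Dusp8 (−10.54), Hspa2 (−10.22), Lhfpl5 (−10.03), Ing5 (−9.63), Hspa4l (−9.56), Tmtc4 (−9.51), Jag1 (−9.32), Gnl3l (−9.24), Sntb1 (−8.94) and Zcchc3 (−8.79). All were lower in the base in the higher series too, in which the random lists above were low as well. The rule already required the same direction in the lower series, where Lhfpl5 was at −0.78. Jag1 and Sntb1 had 0 counts in the base, which allows at most 0.000234 and 0.000305 times the apical level at a limit of 3 counts over the group. The ratio of base to apex was 0.000216 (4.4e-05 to 0.00063) for Gnl3l with 3 counts in the base, and Ing5 and Zcchc3 had 2 each. Hspa2 and Hspa4l encode heat shock proteins and Dusp8 a phosphatase of MAP kinases. In data simulated with no difference, 10.8% of 7742 genes met the rule in OHCs, with ranked values up to 6.55 on the basal side and 8.94 on the apical side. The rule ranks by the smaller of the pooled value and that of the mean of the cells. On that scale Hspa4l (−8.85 in the mean of the cells) and Zcchc3 (−8.79 pooled) lay below the largest simulated apical value. Sntb1 (−8.94 pooled) was about equal to it. The simulated values come from 1 draw with genes independent of each other. Chance is therefore not excluded for these genes, nor for those above the simulated values.

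Regional differences in IHCs and OHCs, which share no cells, were weakly correlated across genes when counts were pooled. Over 15004 genes the Pearson correlation was 0.0794 and the Spearman correlation 0.0811. Data simulated with no regional difference gave a Pearson value of 0.00559 over 13459 genes. They were drawn with genes independent and with no series difference, so that value is near 0 by construction. It does not show what correlation arises without a regional difference. The Pearson value of the real data was 0.0544 in the higher series, 0.150 in the lower and 0.153 with both averaged. It was 0.394, and the Spearman value 0.237, for differences of the cells' medians. Genes higher in the base of both types were Nenf (5.12 in IHCs and 7.98 in OHCs), Vmo1 (5.29 and 4.91), Hbb-bs (4.61 and 5.35), Auh (4.43 and 4.60) and Cldn19 (4.33 and 4.94), and Vmo1, Hbb-bs and Nenf were not below 0 in either series of either type, though Nenf was at 0 and Hbb-bs at 0.49 in OHCs of the higher. Auh was at −0.08 in OHCs of the lower series and Cldn19 at −0.05 in those of the higher. Genes higher in the apex of both types were Socs2 (−6.18 and −6.79), Golph3 (−5.28 and −6.41), Rab11b (−5.01 and −5.21), Sp3 (−5.02 and −4.81) and Dennd5a (−4.70 and −4.98). Golph3, Rab11b and Dennd5a turned in OHCs of the lower series, to 0.68, 0.11 and 0.04. Hbb-bs is a blood gene, and Cldn19 encodes a tight junction protein.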

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

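The tests of series and depth for glycolysis were set before their results were seen, and all other tests here were chosen only after the result was seen. Among groups of 4 to 10 samples, which basal OHCs alone met, 10 of 18 measures had 1 cell whose gap to the next exceeded Dixon's 95% critical share of the range; chance gives this in about 1 in 20 groups. The highest cells had 76.9 CPM of Slc26a5 and 9533 CPM of Ocm (cell 3), 50.6 CPM of Pou4f3 and 1814 CPM of Tmc1 (cell 5), 0.338 CPM of Slc17a8, 0.506 CPM of Chrna9 and 11.1 CPM of Calb1 (cell 4), 1.52 CPM of Otof and 1.52 CPM of Chrna10 (cell 7) and 581 CPM of Pvalb (cell 1). The next highest cell had 1.02 CPM of Tmc1. Basal OHCs of the lower series, which include cells 4 and 7, held only 2 counts of Slc17a8 and 4 of Otof. Flags of such genes thus rest on a few reads. The rate of about 1 in 20 holds for normally distributed values, which single-cell levels are not.

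Further genes had regional differences of opposite direction in the cell types, and the difference was not tested. The basal minus apical log2 ratio of OHCs less that of IHCs was −9.94 for Plekhm1 (4.42 in IHCs and −5.52 in OHCs) and −9.36 for Dync2h1 (4.31 and −5.05). It was 10.17 for Ikbkg (−6.19 and 3.97), 8.32 for Olfr806 (−3.54 and 4.77) and 8.29 for Nat8l (−4.81 and 3.48). Of these 5, Dync2h1 and Olfr806 alone kept both directions in both series. Ikbkg shares exonic bases with G6pdx on the opposite strand.

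Glycolysis genes were higher in basal than in apical IHCs by a median of 1.79. The series argue against their difference as the whole cause, since the value nearer 0 was 1.35 at percentile 98.9, and depth does so too, since among cells as deep as the shallowest basal IHC it was 1.62. RNA of blood, nerve and connective tissue and a change in the IHCs cannot be told apart in either series. The highest-placed of these lists stood at 0.47 (percentile 92.05) in the higher series and at 0.99 (percentile 97.2) in the lower, both within the range of random lists but too near its upper end to exclude such RNA, by 1 bound for both series that was set with the values known. Reads shared with pseudogenes, differences between animals and a regional difference in metabolism were not tested, so all of these may contribute.

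OHC genes stood lower in basal than in apical IHCs, by a median log2 ratio of −1.34. Removing cells with more counts of the other type's markers left −1.42 at percentile 1.68, in a test whose selection lowers OHC markers in the apex. This argues against those cells alone as the whole cause. Cells with many counts of both lists stayed in. Apical IHC cell 5 had 10442 IHC and 9499 OHC marker counts, and cell 11 had 24217 and 14666. Mixed or mislabelled cells are therefore not excluded. A series difference cannot be told apart from a regional one, because the median was −0.04 in the lower series and −1.24 in the higher, within the range of random lists in both. The markers parted in the lower series: Ocm (−6.16), Ikzf2 (−4.69) and Lbh (−1.66) stayed low, and the other 8 were less than 2-fold apart. RNA of neighbouring OHCs in apical libraries may be a source: the SD over markers of their log2 ratio between apical IHCs and OHCs was 0.89, which was too small to exclude this by a bound set with the value known. The pooled proportions were not constant: apical IHCs stood at between 4.47% (Lmod3) and 32.2% (Chrna9) of the apical OHC level. The SD was 0.81 in the higher series and 2.58 in the lower, where several markers lay near 0 in both types. OHC RNA and expression in the IHCs themselves thus cannot be told apart.

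In the pooled basal OHCs, most stereocilia genes were low and genes of other tissues high. Without the deepest cell of each group the stereocilia median was −3.64 at percentile 1.15. In the base that was cell 3, with 104403 counts of OHC markers against at most 7699 in any other basal OHC. Its removal takes hair cell RNA out of the base, so a median that stayed low decides little about 1 deep cell. The series were argued against for the direction, with −0.60 at percentile 0.7 in the lower one, but not for the size. RNA of blood, nerve and connective tissue may be a source, since the lowest of their medians was 1.08, but this was known when the test was set, and supporting cell genes were at 0.14 and the stria vascularis at −3.68. The 2 basal OHCs of the higher series had 16.9% and 14.8% of their counts in genes with mt- symbols. With 8 cells, 2 others of which had more IHC than OHC marker counts, damaged or mixed cells and a regional difference in the OHCs cannot be told apart.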

How the results depend on the processing

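The average of both series, the removal of cells by their markers, the deep-cell subset and OHCs without the base were chosen after seeing the data; the other alternatives were planned. Of the results that answer a comparison, 90 values under alternatives stayed within their interval, 16 moved beyond it and 1 changed sign. Of the others, which leave out single genes under 2-fold, 1455 stayed, 392 moved and 40 changed sign. Among these, single genes counted as staying when they moved by less than 1 log2 unit, and not by an interval. Detected genes counted as staying when they moved by less than the SD of the cells. These counts do not measure robustness, since a wide interval lets a value near 0 count as staying. OHC markers in basal against apical IHCs had an interval of −5.54 to 0.07, so −0.04 in the lower series counted as staying. The interval of the correlation treats genes as independent, which they are not. No paired analysis was possible because the labels name no animal and do not say whether a title number shared by cells of different groups links them. The cause was not tested for any value below. Depth limits basal OHCs most, with 28574809 counts in 8 cells, and the series above 100 holds 2 of them.

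In the lower series the OHC against IHC medians were −0.18 for the lateral wall, −0.34 for neurons and glia, −0.56 for ribosomal proteins and 5.28 for OHC markers, those of basal against apical OHCs 3.01 for ribosomal proteins and −0.60 for the stereocilia bundle, and the correlation between the types 0.150. Basal against apical OHCs turned for Auh (−0.0784), Calb1 (0.44), Chrna10 (0.27), Dennd5a (0.0357), Golph3 (0.68), Kcnma1 (1.95), Plekhm1 (0.0134) and Rab11b (0.11). IHCs turned for Calb1 (0.0175), Calb2 (1.13), Chrna10 (0.12), Nat8l (1.77) and Slc26a5 (0.0561).

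In the higher series basal against apical medians were −0.0209 for mesenchyme and bone, −0.0105 for ribosomal proteins and −5.47 for the stereocilia bundle in OHCs and −0.23 for ribosomal proteins in IHCs, and the correlation was 0.0544. OHCs turned for Cldn19 (−0.0468), Dse (−1.28), Galnt17 (−0.29), Ikbkg (−5.92), Maml3 (−0.20) and Tomm40 (−0.14), IHCs for Plekhm1 (−1.69), and OHCs against IHCs for Srpk2 (−1.01) and Wls (−0.84). Among fixed genes under 2-fold when pooled, Tmc1 (−2.43) and Pvalb (0.20), OHCs against IHCs, Pvalb in OHCs (1.45) and Tmc1 in IHCs (0.0687) turned in this series, and Calb1, OHCs against IHCs (0.20), and Kcnma1 (0.12), Myo7a (−1.77) and Otof (−0.67) in IHCs in the lower.

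The nuclear respiratory chain, OHCs against IHCs, turned to 0.36 with DESeq2 size factors, 0.070 with the filter of 20 CPM, 0.085 with 5 CPM added and 0.30 without basal OHCs. The lateral wall turned to −0.69 with the series averaged and −0.20 without the deepest cells. Ribosomal proteins in OHCs stood at 2.74 with DESeq2 size factors, 2.56 in the mean of the cells, 0.93 in their median and 1.22 with the series averaged, which turned IHCs to −0.0507. As medians of the cells, glycolysis in IHCs was at 0.48 and the stereocilia bundle in OHCs at −0.16, and Calb2 in IHCs (0.0627), Golph3 (0.0874) and Rab11b (0.25) in OHCs turned. The correlation was 0.394 by medians of the cells, 0.101 with 5 CPM added, 0.0979 with the filter of 20 CPM and 0.153 with the series averaged. In OHCs, Ikbkg turned to −0.80 with the series averaged and −4.39 without the deepest cells, and Kcnma1 to 0.22 with the series averaged.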

Other observations

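All checks reported here were chosen only after the result was seen, except the title-number series and the possible repeat. Xist, the RNA of the inactive X chromosome, and genes of the Y chromosome differed between the series. With at least 10 counts as the limit, 49 of 58 cells of the higher series had Y-linked reads alone, none had Xist alone and 9 had neither. In the lower series 19 of 81 cells had Y-linked reads alone, 11 had Xist alone and 51 had neither. Among the lower series, Xist alone occurred in 4 apical and 4 basal IHCs, 2 apical OHCs and 1 basal OHC. Y-linked reads alone occurred in 14 IHCs and 4 OHCs of the middle and in 1 apical OHC. Among the lower-series cells with such reads, sex and region were thus nearly inseparable, with the middle set against apex and base.

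Of all cells, 8 had more counts of the other type's marker list than of their own: 3 of 34 apical and 1 of 34 middle IHCs, 2 of 23 middle and 2 of 8 basal OHCs. The other cells are not thereby shown to be of their labelled type. Some had few counts of their own list, such as 22.5 CPM in middle OHC cell 23 and 80.0 CPM in basal OHC cell 4. In the median cell the OHC markers held 0.888% of the counts in apical OHCs, 0.207% in middle and 0.041% in basal ones. Mesenchyme and bone genes held 1.63% of the counts of basal OHCs and 0.160% of those of apical OHCs, and blood and immune genes 1.47% and 0.273%. The median share of all genes with mt- symbols ran from 1.94% in basal IHCs to 5.1% in apical OHCs. It was 2.56% in basal OHCs, but 15.8% in the 2 of the higher series, where the 10 highest genes held 50.3% and 46.3% of the counts, and 2.05% in the 6 of the lower.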
